A study of Homo sapiens with 6 samples.

How the data were processed

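The study sequenced RNA from RMS13 rhabdomyosarcoma cells, bought from a cell bank, and from an acquired-resistance line made from them, after 9 h with 10 µM MAL3-101 or with DMSO. Per the labels' protocols, cells grew in medium with serum, total RNA was taken with a column kit, and paired-end libraries were made with a TruSeq kit. Per the submitters' processing notes, RSEM, DESeq and the genome build hg19 were used; their versions, the aligner, the annotation and whether counting used strand are not given in the sources used here. The deposited files hold TPM per gene name, 1 file per library, with 2 decimals, and each library sums to 1000000 apart from rounding. Expected counts had been assumed before the data were examined. As the files hold TPM, no count model was run, and the test planned for normalized values was used. TPM keeps no depth, so the reads behind a value are unknown, and no interval or floor from counting is given.

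Samples were grouped by the titles and descriptions of the labels into 3 groups of 2 libraries. The DMSO titles also carry the drug's name, and the descriptions, which name DMSO, were followed. Genes with a mean of 1 TPM or more in at least 1 group were tested, 15148 of them in all. Values were taken as log2(TPM + 1), so a fold change understates the change of genes with low levels. limma 3.58.1 in R 4.3.3 fitted group means over all 6 libraries with a mean-variance trend, which leaves 3 residual degrees of freedom and adds 4.17 prior ones; the median standard error of a log2 fold change was 0.105. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Levels are given as mean ± SD of 2 libraries, and log2 fold changes with their moderated SE.

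Before the data were examined, 33 gene lists were fixed on stress responses, metabolism, growth, signalling, muscle lineage, drug efflux, RNA quality and markers of other cell types. Of their 954 members, 953 were found in the files, 6 of them under another symbol. The 29 lists with 5 or more tested members were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Camera compares the test statistics of a list's genes with those of all other tested genes. Its p-value and direction are relative to those genes, and the median printed beside them was not itself tested. With an estimated correlation camera called 0 lists in each of the 3 comparisons, and 3 lists in each had an unadjusted p under 0.05, while fry, which asks whether a list's genes move on balance 1 way and compares them with no other genes, called 17, 22 and 15. Calls were lost also for lists whose estimated correlation lay below 0.01, so a larger correlation does not account for every loss. Where a list's median, mean and test differ in sign, this is stated beside it. The genes named are those of a rule fixed beforehand, from which the text takes a part: the 10 largest rises and 10 largest falls among called genes with a group mean of 5 TPM or more and no overlap between replicates, up to 4 called members per list with the largest change, and 19 stress, muscle and resistance genes in every case. Overlapping and antisense genes cannot be told apart without strand.

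Gene types, transcript lengths and GC content came by name from GENCODE release 29, and the order of genes along chromosomes from RefSeq on GRCh38.p14. As the files rest on hg19, no coordinates are given. The code was tested on simulated libraries made from the real means and spreads. Of genes changed by 0.5, 1 and 2 on the log2 scale, the fit recovered 43.3%, 85.1% and 97.0% for parental MAL3-101 against DMSO, 40.3%, 77.6% and 100% for resistant against parental MAL3-101, and 58.2%, 88.1% and 100% for resistant MAL3-101 against DMSO, with 4.46%, 2.03% and 2.38% of calls false. Each percentage recovered rests on 66 or 67 changed genes among 15148, drawn only from genes above a floor of mean level. Recovery of genes with low levels was therefore not measured. Far fewer genes were changed in the simulation than were called in the data, so its recovered and false shares need not carry over. For comparisons that share the DMSO libraries, 100 sets of unchanged groups were simulated. Alternatives were other pseudocounts, no filter and a stricter one, only the libraries compared, a replicate block, each library left out in turn, a fold threshold, scaling by median ratio or upper quartile, TPM without mitochondrial genes, and protein-coding genes alone; the last 4 were chosen after seeing the data. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 served for the neighbour tests and figures.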

Results

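RNA sequencing measured transcript levels in 6 libraries from RMS13, a human rhabdomyosarcoma cell line of the alveolar type, and from RMS13-R, a line derived from it that had acquired resistance to MAL3-101. MAL3-101 is a small-molecule inhibitor of the HSP70 family of chaperones, and DMSO was its vehicle. The 3 groups held 2 libraries each, named A and B: parental cells with DMSO, parental cells with 10 µM MAL3-101 and resistant cells with 10 µM MAL3-101, all for 9 h. Resistant cells without the drug were not analysed here, so a difference between resistant and parental libraries can belong to the line, to its response to the drug, or to both. The labels do not say whether A and B were separate cultures, so the p-values measure only the spread between these libraries, pooled over the 3 groups. Values are in TPM, transcripts per 1000000, for each gene name, a unit that keeps no read depth, so the counting error of a value is unknown.

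The libraries grouped by line and treatment. Between 13918 and 14334 genes stood at 1 TPM or more in each library. Replicates correlated at r = 0.990 across genes with DMSO, 0.995 in parental cells with MAL3-101 and 0.996 in resistant cells, where genes are not independent replicates. The DMSO pair spread most: 171 of 15148 tested genes differed 2-fold between its libraries, against 67 and 40 in the parental and resistant MAL3-101 pairs. The first principal component held 62.7% of the variance and set both resistant libraries apart from the other 4. The second held 27.1% and separated parental MAL3-101 from parental DMSO libraries. Mitochondrial ribosomal RNA made up 1.92% and 1.97% of TPM in the parental MAL3-101 libraries, 0.533% and 0.565% with DMSO, and 0.784% and 0.767% in resistant cells.

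In parental cells, 9 h of MAL3-101 went with a rise of stress-response and immediate-early transcripts. DDIT3, which encodes the stress-induced transcription factor CHOP, stood at 2287 ± 37.6 TPM (SD, n = 2) against 130.3 ± 2.82 TPM with DMSO, a log2 fold change of 4.12 (SE 0.05). HSPA6, a strictly inducible HSP70 gene, rose from 1.48 ± 0.453 TPM to 286 ± 55.8 TPM, by 6.85 (SE 0.17), and EGR1, an immediate-early zinc finger factor, from 9.64 ± 2.24 TPM to 467 ± 15.6 TPM, by 5.47 (SE 0.13). HSPA8, the constitutive cytosolic HSP70, went the other way, with a log2 fold change of -0.75 (SE 0.09). By limma's moderated test, 6181 of 15148 genes changed at a Benjamini-Hochberg adjusted p under 0.05, 3429 of them higher and 2752 lower with MAL3-101. The majority direction depended on scaling, with 3203 higher and 3135 lower after median-ratio and 3106 and 3215 after upper-quartile scaling. Changes of 2-fold or more were mostly rises, 426 against 103. Without parental MAL3-101 library A the count of changed genes was 3169 (1801 higher and 1368 lower), and without its library B 3397 (1936 and 1461). Tested against a fold of 1.5, 346 genes passed.

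The targets of ATF4 and CHOP, the transcription factors of the integrated stress response, rose nearly throughout: 38 of 40 rose, 0 fell and 2 did not pass (39 rose and 0 fell adjusted over the list alone). INHBE, TRIB3 and CHAC1 had log2 fold changes of 4.69 (SE 0.11), 4.49 (SE 0.10) and 4.02 (SE 0.16), and ATF4 itself one of 1.39 (SE 0.04). The list, with a median of 1.87, had an adjusted p = 1.3e-25 by camera and an adjusted p = 0.103 with an estimated correlation. Cytosolic aminoacyl-tRNA synthetases, many of which are ATF4 targets, followed, with 13 rises, 2 falls and 5 not past the test among 20 genes (the same adjusted over the list alone). CARS rose by 2.04 (SE 0.07) and GARS by 1.82 (SE 0.05). A median of 0.74 went with adjusted p = 7.5e-06 by camera and adjusted p = 0.199 with an estimated correlation. Among chaperones and degradation factors of the endoplasmic reticulum, 32 of 37 rose, 2 fell and 3 did not pass (the same adjusted over the list alone). HERPUD1 rose by 2.85 (SE 0.08), XBP1, the transcription factor of the unfolded protein response, by 2.74 (SE 0.05), and HSPA5, the HSP70 of that compartment, by 2.15 (SE 0.05), to 2842 ± 93.1 TPM. Their median was 0.70 (adjusted p = 9.1e-15 by camera, and adjusted p = 0.227 with an estimated correlation).

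Cytosolic heat shock genes, the targets of HSF1, rose in part: 21 of 34 rose, 3 fell and 10 did not pass (23 rose and 3 fell adjusted over the list alone). DNAJB1 and BAG3, co-chaperones of HSP70, rose by 2.73 (SE 0.07) and 2.78 (SE 0.10), and HSPH1 by 1.47 (SE 0.07). HSPA1A and HSPA1B encode the same inducible HSP70 in near-identical copies, so the division of reads between them is uncertain; their summed level was 2451 ± 339 TPM (SD, n = 2) with MAL3-101 and 136 ± 2.28 TPM with DMSO. The list, with a median of 0.52, had an adjusted p = 7.4e-07 by camera and an adjusted p = 0.460 with an estimated correlation. In the HSP70 and HSP110 family, 9 of 14 rose, 1 fell and 4 did not pass (the same adjusted over the list alone). A median of 1.05 went with adjusted p = 2.7e-05 by camera and adjusted p = 0.460 with an estimated correlation. Subunits of the 26S proteasome moved the other way by small amounts: 0 of 34 rose, 25 fell and 9 did not pass (0 rose and 27 fell adjusted over the list alone), with PSMD2 at -0.55 (SE 0.05) and PSMB3 at -0.51 (SE 0.07). Their median was -0.28 (adjusted p = 5.6e-09 by camera, and adjusted p = 0.460 with an estimated correlation).

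Of the immediate-early genes and feedback regulators of the MAP kinase pathway, 25 of 34 rose, 1 fell and 8 did not pass (26 rose and 1 fell adjusted over the list alone). FOS rose by 4.44 (SE 0.11) and ATF3 by 2.97 (SE 0.06). The list, with a median of 1.02, had an adjusted p = 4.1e-11 by camera and an adjusted p = 0.460 with an estimated correlation. NF-kB targets and cytokines gave 9 rises, 2 falls and 7 not past the test among 18 genes (9 rises and 3 falls adjusted over the list alone), where IL8 rose by 3.74 (SE 0.17) while CCL2 fell by 1.65 (SE 0.31); CCL2 stood at 6.67 and 14.5 TPM in the DMSO libraries A and B. A median of 0.30 went with adjusted p = 0.049 by camera and adjusted p = 0.561 with an estimated correlation. That call was lost in several settings, among them without DMSO library A (adjusted p = 0.396) and without parental MAL3-101 library A (adjusted p = 0.070). Targets of p53 gave 14 rises, 2 falls and 8 not past the test among 24 genes (the same adjusted over the list alone), among them SESN2 at 3.48 (SE 0.08), PMAIP1 at 1.55 (SE 0.09) and CDKN1A, the cell cycle inhibitor p21, at 1.34 (SE 0.09). Their median was 0.30 (adjusted p = 0.002 by camera, and adjusted p = 0.505 with an estimated correlation). SESN2 and TNFRSF10B also belong to the ATF4 and CHOP list.

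Genes of DNA replication and the G1/S transition fell, with 1 rises, 26 falls and 9 not past the test among 36 genes (1 rises and 28 falls adjusted over the list alone). CCND1, which encodes cyclin D1, had a log2 fold change of -1.38 (SE 0.21) and PCNA, the replication clamp, one of -0.82 (SE 0.08). The list, with a median of -0.38, had an adjusted p = 3.9e-09 by camera and an adjusted p = 0.505 with an estimated correlation. Mitotic and G2/M genes gave 2 rises, 14 falls and 24 not past the test among 40 genes (2 rises and 16 falls adjusted over the list alone), a call lost without DMSO library A (adjusted p = 0.054) and by fry (adjusted p = 0.120). A median of -0.14 went with adjusted p = 0.003 by camera and adjusted p = 0.561 with an estimated correlation. Ribosome biogenesis genes and MYC targets gave 4 rises, 11 falls and 15 not past the test among 30 genes (6 rises and 16 falls adjusted over the list alone), a call lost without DMSO library B (adjusted p = 0.092) and by fry (adjusted p = 0.117). NOP56 had a log2 fold change of -0.89 (SE 0.07), and MYC itself rose by 0.81 (SE 0.11). Their median was -0.16 (adjusted p = 0.004 by camera, and adjusted p = 0.599 with an estimated correlation). Genes of cholesterol synthesis and uptake gave 14 rises, 2 falls and 8 not past the test among 24 genes (the same adjusted over the list alone), STARD4 with 1.27 (SE 0.06) and HSD17B7 with 1.22 (SE 0.08). The list, with a median of 0.36, had an adjusted p = 8.9e-05 by camera and an adjusted p = 0.470 with an estimated correlation. Mitochondrially encoded mRNAs gave 0 rises, 7 falls and 6 not past the test among 13 genes (0 rises and 10 falls adjusted over the list alone), in the libraries in which the mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2, chosen after their values were seen, were higher by 2.06 (SE 0.06) and 1.75 (SE 0.06). A median of -0.32 went with adjusted p = 2.3e-04 by camera and adjusted p = 0.508 with an estimated correlation. Fry did not call them (adjusted p = 0.069). Of 17 markers of epithelial cells, a cell type the culture is not labelled to hold, 5 were tested, and 4 of 5 rose, 0 fell and 1 did not pass (5 rose and 0 fell adjusted over the list alone), OCLN with 0.90 (SE 0.08) and KRT18 with 1.12 (SE 0.27), which did not pass without parental MAL3-101 library A (1.09) or B (1.16). Their median was 0.81 (adjusted p = 0.016 by camera, and adjusted p = 0.460 with an estimated correlation). Without DMSO library A that call was lost (adjusted p = 0.054).

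**Figure D1:**
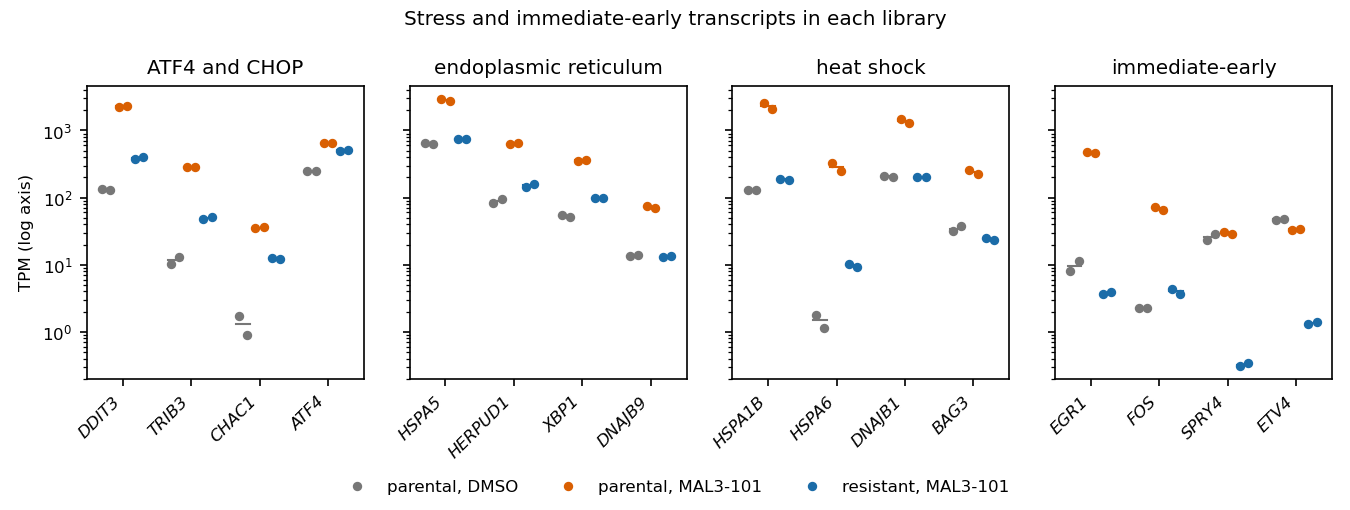
Levels of 16 transcripts in TPM on a log axis, with 1 point per library and a short line at the mean of each group of 2 (grey, parental DMSO; orange, parental MAL3-101; blue, resistant MAL3-101). DDIT3 averaged 2287 TPM in parental MAL3-101 libraries and 386 TPM in resistant ones, and EGR1 467 and 3.79 TPM.

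With MAL3-101 in both, resistant cells had lower levels of the stress and immediate-early transcripts than parental cells. EGR1 stood at 3.79 ± 0.148 TPM (SD, n = 2) in resistant and 467 ± 15.6 TPM in parental libraries, a log2 fold change of -6.61 (SE 0.13). DDIT3 stood at 386 ± 21.9 TPM, -2.57 (SE 0.05) on the log2 scale, and HSPA1A and HSPA1B together at 198 ± 2.79 TPM against 2451 ± 339 TPM. PTGIS, which encodes prostacyclin synthase, was higher in resistant cells, from 0.470 ± 0.255 TPM to 31.6 ± 0.0212 TPM, by 4.48 (SE 0.16). By limma's test 8495 of 15148 genes differed at an adjusted p under 0.05, 3228 higher and 5267 lower in resistant cells, with 476 at least 2-fold higher and 1146 at least 2-fold lower. After median-ratio scaling 4082 were higher and 4467 lower. The count of higher genes was 2124 without resistant library B. Tested against a fold of 1.5, 1604 genes passed.

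Every tested member of the immediate-early and MAP kinase feedback list was lower in resistant cells: 0 of 34 were higher, 34 lower and 0 did not pass (the same adjusted over the list alone). SPRY4, an inhibitor of growth factor signalling, had a log2 fold change of -4.54 (SE 0.13), and ETV4, a transcription factor induced by that pathway, of -3.88 (SE 0.08). The list, with a median of -1.98, had an adjusted p = 1.1e-13 by camera and an adjusted p = 0.397 with an estimated correlation. NF-kB targets and cytokines gave 1 higher, 15 lower and 2 not past the test among 18 genes (the same adjusted over the list alone), IL8 with -4.20 (SE 0.17) and IL11 with -3.41 (SE 0.24). A median of -1.39 went with adjusted p = 0.001 by camera and adjusted p = 0.591 with an estimated correlation. Interferon-stimulated genes gave 0 higher, 14 lower and 4 not past the test among 18 genes (0 higher and 15 lower adjusted over the list alone), BST2 with -3.21 (SE 0.29) and IRF1 with -1.73 (SE 0.10). Their median was -0.84 (adjusted p = 3.5e-04 by camera, and adjusted p = 0.244 with an estimated correlation).

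Targets of ATF4 and CHOP gave 1 higher, 35 lower and 4 not past the test among 40 genes (2 higher and 35 lower adjusted over the list alone). GDF15, a stress-induced secreted factor, fell by 3.36 (SE 0.07) and TRIB3 by 2.51 (SE 0.10) on the log2 scale, ATF4 by 0.38 (SE 0.04). The list, with a median of -1.23, had an adjusted p = 3.2e-10 by camera and an adjusted p = 0.244 with an estimated correlation. The tRNA synthetases gave 2 higher, 16 lower and 2 not past the test among 20 genes (the same adjusted over the list alone), YARS with -1.71 (SE 0.05). A median of -0.63 went with adjusted p = 1.8e-04 by camera and adjusted p = 0.244 with an estimated correlation. Endoplasmic reticulum chaperones and degradation factors gave 3 higher, 27 lower and 7 not past the test among 37 genes (3 higher and 28 lower adjusted over the list alone), with DNAJB9 at -2.38 (SE 0.07) and HSPA5 at -1.92 (SE 0.05). Their median was -0.59 (adjusted p = 1.1e-06 by camera, and adjusted p = 0.397 with an estimated correlation). Heat shock genes gave 2 higher, 27 lower and 5 not past the test among 34 genes (the same adjusted over the list alone), BAG3 with -3.26 (SE 0.10) and DNAJB1 with -2.75 (SE 0.07). The list, with a median of -0.92, had an adjusted p = 3.8e-07 by camera and an adjusted p = 0.458 with an estimated correlation. The HSP70 family gave 1 higher, 10 lower and 3 not past the test among 14 genes (the same adjusted over the list alone); the higher gene, HSPA12A, an atypical member, went from 0.610 ± 0.269 TPM to 14.8 ± 0.537 TPM, while HSPA8 had a log2 fold change of 0.10 (SE 0.09), adjusted p = 0.368, but passed without DMSO library A or B at the same value. A median of -1.15 went with adjusted p = 0.002 by camera and adjusted p = 0.458 with an estimated correlation.

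Genes of the BCL2 family and death receptor pathways gave 3 higher, 15 lower and 6 not past the test among 24 genes (3 higher and 16 lower adjusted over the list alone). PMAIP1, a pro-apoptotic BH3-only gene, had a log2 fold change of -2.11 (SE 0.09), and MCL1, an anti-apoptotic member of the family, one of -1.19 (SE 0.04). Their median was -0.36 (adjusted p = 0.009 by camera, and adjusted p = 0.372 with an estimated correlation). Targets of p53 gave 5 higher, 14 lower and 5 not past the test among 24 genes (the same adjusted over the list alone), GADD45A with -2.21 (SE 0.05), a call lost without DMSO library A (adjusted p = 0.059) or B (adjusted p = 0.059). The list, with a median of -0.31, had an adjusted p = 0.049 by camera and an adjusted p = 0.629 with an estimated correlation. That call was also lost with a pseudocount of 0.1 (adjusted p = 0.052) and over protein-coding genes alone (adjusted p = 0.093).

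Other lists lay upward of the remaining genes in resistant cells by camera, while epithelial markers were lower. The proteasome gave 19 higher, 3 lower and 12 not past the test among 34 genes (the same adjusted over the list alone), PSMB1 with 0.88 (SE 0.04). A median of 0.21 went with adjusted p = 3.0e-05 by camera and adjusted p = 0.522 with an estimated correlation. Mitochondrially encoded mRNAs gave 12 higher, 0 lower and 1 not past the test among 13 genes (the same adjusted over the list alone), while MT-RNR1 had a log2 fold change of -2.22 (SE 0.06). Their median was 0.47 (adjusted p = 9.6e-05 by camera, and adjusted p = 0.591 with an estimated correlation). Cytosolic ribosomal proteins gave 36 higher, 8 lower and 30 not past the test among 74 genes (the same adjusted over the list alone), RPLP1 with 0.48 (SE 0.05). The list, with a median of 0.14, had an adjusted p = 1.4e-04 by camera and an adjusted p = 0.591 with an estimated correlation. Mitotic genes gave 23 higher, 6 lower and 11 not past the test among 40 genes (23 higher and 7 lower adjusted over the list alone), among them AURKA, a mitotic kinase, with 0.83 (SE 0.06). A median of 0.24 went with adjusted p = 1.6e-04 by camera and adjusted p = 0.591 with an estimated correlation. Replication and G1/S genes gave 11 higher, 6 lower and 19 not past the test among 36 genes (the same adjusted over the list alone). Their median lay above 0 and the test pointed up relative to the other genes, but their mean was -0.0014. TYMS was at 0.85 (SE 0.05) against CCND1 at -3.21 (SE 0.21). The median of the list was 0.10 (adjusted p = 0.022 by camera, and adjusted p = 0.847 with an estimated correlation). By fry that call was lost (adjusted p = 0.474). Genes of cholesterol synthesis and uptake gave 13 higher, 6 lower and 5 not past the test among 24 genes (the same adjusted over the list alone), LSS with 1.14 (SE 0.09) and STARD4 with -1.10 (SE 0.06). The list, with a median of 0.36, had an adjusted p = 0.003 by camera and an adjusted p = 0.591 with an estimated correlation. Among the markers of epithelial cells, 0 of 5 were higher, 5 lower and 0 did not pass (the same adjusted over the list alone), KRT18 from 16.6 ± 0.601 TPM to 0.110 ± 0.0707 TPM. A median of -2.50 went with adjusted p = 0.004 by camera and adjusted p = 0.397 with an estimated correlation. With no filter on low values that call was lost (adjusted p = 0.258).

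**Figure D2:**
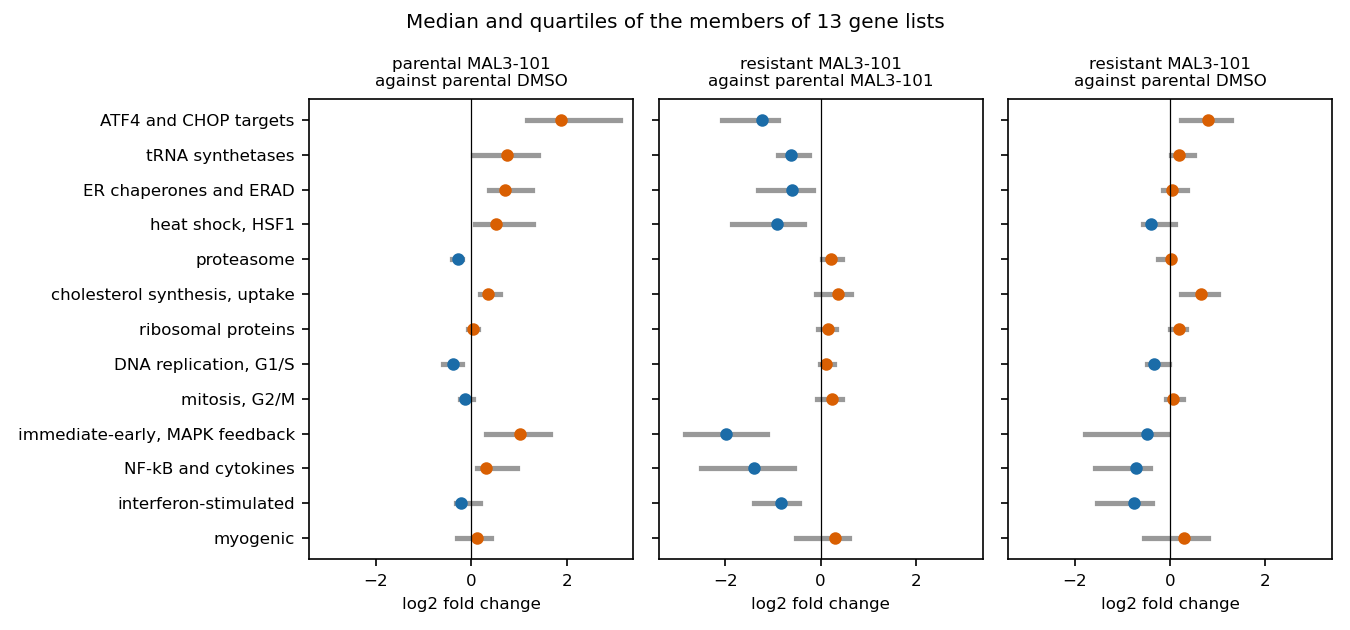
Median (point) and quartiles (bar) of the log2 fold changes of the tested members of 13 gene lists in the 3 comparisons, orange for a median above 0 and blue for one below. The ATF4 and CHOP targets had medians of 1.87, -1.23 and 0.80 from left to right, and the immediate-early list 1.02, -1.98 and -0.49.

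The myogenic programme of the tumour line differed gene by gene between the 2 lines. Among muscle determination and differentiation genes, 15 of 34 were higher, 11 lower and 8 did not pass (the same adjusted over the list alone), without a call (adjusted p = 0.282 by camera). Their median was 0.30 and camera pointed up, but their mean was -0.12 and fry called them downward (adjusted p = 0.026). TNNT1, a slow skeletal troponin, had a log2 fold change of -3.54 (SE 0.10) and CHRNA1, an acetylcholine receptor subunit, of -2.60 (SE 0.08). The determination factor MYOD1 was at -0.56 (SE 0.04) and the differentiation factor MYOG at 0.53 (SE 0.19), a difference that did not pass without any 1 of the 4 libraries compared (0.51 to 0.55 on the log2 scale). Genes reported in the field as downstream of the PAX3-FOXO1 fusion gave 9 higher, 7 lower and 10 not past the test among 26 genes (the same adjusted over the list alone), IGF2 with 1.66 (SE 0.06) and FGFR4 with -0.96 (SE 0.07). That list was not called (adjusted p = 0.524 by camera), and its median, -0.10, and mean, -0.083, lay below 0 while the test pointed up. PAX3 had a log2 fold change of 0.61 (SE 0.06). Efflux transporters and detoxifying enzymes gave 7 higher, 8 lower and 6 not past the test among 21 genes (8 higher and 8 lower adjusted over the list alone). They too were without a call (adjusted p = 0.524 by camera), with a median of -0.22, a mean of 0.006 and a test that pointed up. Camera's direction is relative to the other genes, and the median of all genes in this comparison was -0.099. ABCB1, the multidrug efflux pump, was listed at 0 TPM with DMSO, averaged 0.08 TPM in parental and 0.01 TPM in resistant MAL3-101 libraries, and was not tested.

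Against parental cells with DMSO, resistant cells with MAL3-101 had part of the integrated stress response above the vehicle level, while most tested members of the interferon list and 21 of 34 immediate-early and feedback genes lay below it. DDIT3 averaged 386 ± 21.9 TPM (SD, n = 2) against 130.3 ± 2.82 TPM, a log2 fold change of 1.56 (SE 0.05). CHAC1 rose by 2.56 (SE 0.16) and TRIB3 by 1.97 (SE 0.10), whereas DNAJB1 had a log2 fold change of -0.02 (SE 0.07), adjusted p = 0.845, and 0.0443 after median-ratio scaling. CCND1 lay lower, at 3.14 ± 0.509 TPM against 101 ± 34.9 TPM, a log2 fold change of -4.58 (SE 0.21), as did ETV4, at 1.35 ± 0.0848 TPM against 47.8 ± 1.38 TPM, one of -4.38 (SE 0.08). By limma's test 7662 of 15148 genes differed at an adjusted p under 0.05, 3160 higher and 4502 lower, and 3821 and 3955 after median-ratio scaling. At 2-fold or more, 560 were higher and 796 lower. The count was 5001 (2020 higher and 2981 lower) without resistant library A and 5013 (1917 higher) without its library B. Tested against a fold of 1.5, 1244 genes passed.

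Targets of ATF4 and CHOP gave 29 higher, 4 lower and 7 not past the test among 40 genes (31 higher and 4 lower adjusted over the list alone), with ATF4 at 1.01 (SE 0.04) and STC2 at -2.07 (SE 0.13). Their median was 0.80 (adjusted p = 2.9e-09 by camera, and adjusted p = 0.285 with an estimated correlation). The tRNA synthetases gave 11 higher, 3 lower and 6 not past the test among 20 genes (12 higher and 3 lower adjusted over the list alone), CARS with 0.96 (SE 0.07) and HARS with -1.02 (SE 0.05). The list, with a median of 0.18, had an adjusted p = 0.013 by camera and an adjusted p = 0.481 with an estimated correlation. HARS lies at the end of a run of 82 neighbouring genes, 65 of them lower in resistant cells. Genes of cholesterol synthesis and uptake were mostly higher: 19 of 24 were higher, 1 lower and 4 did not pass (20 higher and 1 lower adjusted over the list alone), MVD with 1.39 (SE 0.08) and HMGCS1 with 1.19 (SE 0.09). A median of 0.65 went with adjusted p = 1.3e-08 by camera and adjusted p = 0.603 with an estimated correlation. Ribosomal proteins gave 37 higher, 8 lower and 29 not past the test among 74 genes (40 higher and 8 lower adjusted over the list alone), RPL37A with 0.70 (SE 0.06). Their median was 0.20 (adjusted p = 2.9e-05 by camera, and adjusted p = 0.806 with an estimated correlation).

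Immediate-early and MAP kinase feedback genes gave 6 higher, 21 lower and 7 not past the test among 34 genes (7 higher and 23 lower adjusted over the list alone), with DUSP6, a phosphatase of ERK, at -2.67 (SE 0.10) and SPRY4 at -4.33 (SE 0.13). The list, with a median of -0.49, had an adjusted p = 0.009 by camera and an adjusted p = 0.806 with an estimated correlation. Interferon-stimulated genes gave 0 higher, 15 lower and 3 not past the test among 18 genes (1 higher and 16 lower adjusted over the list alone), BST2 with -3.42 (SE 0.29) and IFITM3 with -2.20 (SE 0.21). A median of -0.75 went with adjusted p = 1.8e-04 by camera and adjusted p = 0.285 with an estimated correlation. NF-kB targets gave 2 higher, 11 lower and 5 not past the test among 18 genes (2 higher and 15 lower adjusted over the list alone); CCL20 was listed at 0 TPM in both resistant libraries and at 4.87 ± 0.453 TPM with DMSO. Their median was -0.71 (adjusted p = 0.013 by camera, and adjusted p = 0.806 with an estimated correlation). Ribosome biogenesis genes gave 3 higher, 19 lower and 8 not past the test among 30 genes (4 higher and 20 lower adjusted over the list alone), NOLC1 with -1.02 (SE 0.04). The list, with a median of -0.37, had an adjusted p = 0.004 by camera and an adjusted p = 0.806 with an estimated correlation. Replication and G1/S genes gave 3 higher, 20 lower and 13 not past the test among 36 genes (4 higher and 20 lower adjusted over the list alone), CDC25A with -1.55 (SE 0.07), a call lost without DMSO library A (adjusted p = 0.056). A median of -0.34 went with adjusted p = 0.011 by camera and adjusted p = 0.806 with an estimated correlation. Heat shock genes were not called as a list by camera (adjusted p = 0.076) but were called downward by fry (adjusted p = 0.029): 6 of 34 were higher, 20 lower and 8 did not pass (the same adjusted over the list alone), with HSPH1 at -0.93 (SE 0.07) and HSPB8 at -1.81 (SE 0.17). Endoplasmic reticulum chaperones and degradation factors gave 16 higher, 7 lower and 14 not past the test among 37 genes (17 higher and 8 lower adjusted over the list alone) and a median of 0.05, without a call by camera (adjusted p = 0.064) but with one upward by fry (adjusted p = 0.021). Markers of epithelial cells gave 1 higher, 4 lower and 0 not past the test among 5 genes (the same adjusted over the list alone) and a median of -1.90, not called by camera (adjusted p = 0.098) but called by fry (adjusted p = 0.003). The summed HSPA1A and HSPA1B level was 198 ± 2.79 TPM against 136 ± 2.28 TPM with DMSO, and the myogenic list gave 17 higher, 10 lower and 7 not past the test among 34 genes (the same adjusted over the list alone), with a median of 0.29 and a mean of -0.05 (adjusted p = 0.114 by camera, upward). MYOG was at 0.73 (SE 0.19), which did not pass without resistant library A (0.75) or B (0.71), and PAX3 at 1.04 (SE 0.06).

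Both MAL3-101 groups were then set against the same DMSO libraries to ask how far the 2 sets of differences went together, of which that of the resistant cells holds the line as well as the drug. Of the 426 genes that rose at least 2-fold in parental cells, 181 were also above DMSO in resistant cells, 178 did not pass the test and 67 were below it. Set against parental MAL3-101 directly, 371 of the 426 were lower in resistant cells, 14 were higher and 41 did not pass. These genes were chosen for their level in the same parental MAL3-101 libraries, which alone favours lower values. Across 15148 genes the fold changes of the 2 comparisons that share these libraries correlated at r = -0.425. Simulations of unchanged groups gave -0.501, a value that follows from equal group sizes and spread and cannot size the effect. Their covariance was -0.0103, against -0.135 in the data, which is larger in size than sharing alone gave. The median share of the log2 rise present in resistant cells was 0.177 over the 426 genes. Per direction, 1187 genes were higher in both comparisons and 1434 were lower in both, while 659 were higher in parental and lower in resistant cells and 295 the reverse. Independent lists of these sizes would share 715, 818, 1019 and 574 genes, in that order. The part of these counts due to the shared DMSO libraries was not simulated. The fold changes of the 2 MAL3-101 groups against DMSO correlated at r = 0.293 across 15148 genes. From sharing these controls, 100 simulations of unchanged groups gave 0.499, a value that follows from equal group sizes and spread. True differences in either group move the correlation away from it, so a lower value does not show less agreement. The covariance was 0.0881 against a simulated 0.0103, a difference of 0.0778. With a different single DMSO library for each comparison, which leaves 1 library per control, the correlation was 0.179 or 0.228, and without DMSO library A it was 0.385.

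**Figure D3:**
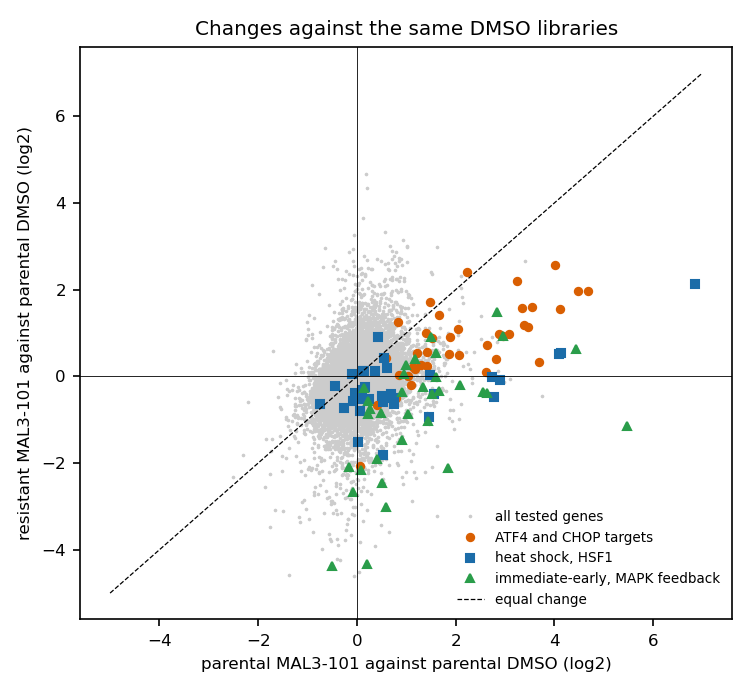
Log2 fold changes of 15148 genes in parental (x axis) and resistant (y axis) MAL3-101 libraries against the same parental DMSO libraries, with members of 3 lists coloured and a dashed line at equal change. ATF4 and CHOP targets lie mostly to the right of 0 on the x axis, between 0 and the dashed line on the y axis, with medians of 1.87 and 0.80.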

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

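The test of a wrong label, the test on mitochondrial mRNAs and the choice of the genes below were made after the results were seen, and the test by median-ratio scaling was chosen after the data were examined but before its result was seen. Parental and resistant MAL3-101 libraries lay on opposite sides of parental DMSO, by at least 2-fold each, for some genes, each with the difference between the 2 groups itself past limma's test. The resistant value holds the line as well as the drug. Of these genes, 22 were above DMSO in parental and below it in resistant cells, and 1, SLITRK5, did the reverse. At 2-fold or more against DMSO, 426 of 15148 genes were higher and 103 lower in parental cells, and 560 higher and 796 lower in resistant cells. Whether 22 and 1 differ from the overlap of unrelated lists of these sizes was not tested, so the counts alone show no opposite response. From the 22, the 4 with the greatest differences are given. EGR1 stood at 5.47 in parental and -1.13 in resistant libraries against DMSO, a difference of -6.61 on the log2 scale. GP6, at 18.8 and 7.97 TPM in the DMSO libraries A and B, differed by -4.84, with 39.8 ± 0.764 TPM in parental and 0.425 ± 0.148 TPM in resistant MAL3-101 libraries. KRT18, an epithelial keratin, differed by -3.99, and FOSL1, an AP-1 subunit that stood at 2.77 and 15.9 TPM in the DMSO libraries A and B, by -3.97. Against DMSO in parental cells, GP6 did not pass without parental MAL3-101 library A (1.60 on the log2 scale), and KRT18 (1.09 and 1.16) and FOSL1 (1.73 and 1.98) without A or without B. In resistant cells FOSL1 did not pass without resistant library A (-2.21) or B (-2.02). SLITRK5 differed by 2.26, with 12.9 ± 0.926 TPM in DMSO, 5.96 ± 0 TPM in parental and 32.4 ± 0.0990 TPM in resistant MAL3-101 libraries.

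Stress genes raised in parental MAL3-101 libraries lay lower in resistant ones. If the resistant libraries were DMSO libraries under a wrong label, few genes would separate them from the DMSO pair, and 7662 did. Scaling of the TPM values is argued against as well, because after median-ratio scaling the ATF4 and CHOP list still had a median of -1.14 between resistant and parental MAL3-101 libraries. Whether the drug acted on the resistant cultures cannot be told apart from a level the line carries without drug: the list's median of 0.80 above parental DMSO is what either could give, since no resistant library without drug was analysed here. A different response of the resistant line stays open as an untested biological explanation.

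Mitochondrial ribosomal RNA was higher in parental MAL3-101 libraries, MT-RNR1 by 2.06 and MT-RNR2 by 1.75 on the log2 scale. A general gain of mitochondrial RNA is argued against, since the 13 mitochondrial mRNAs had a median of -0.32, with 7 lower and 0 higher. More RNA without poly(A) tails in those libraries cannot be told apart from a change in the cells: the histone transcripts, which lack such tails, had a median of 0.38, between the bounds of 0.5 and 0.2 set for and against it, with 3 of 14 higher. An effect of the drug on these RNAs stays open as well.

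Neighbouring genes differed together between resistant and parental libraries. Over 13070 genes placed in chromosome order, log2 fold changes of genes 10 places apart correlated at 0.153 in resistant MAL3-101 against DMSO. That lies above the highest of 1000 shuffled orders, 0.0318, which argues against reads shared by adjacent genes as the cause at that distance. At 1 place the correlation was 0.280, and the part of shared reads in it was not tested. After regression on GC content, length and level the correlation at 10 places was 0.151, so shared composition is not its whole cause. In parental MAL3-101 against DMSO it was 0.0325, above its own highest shuffle of 0.0227, and 0.0153 after that regression. The difference of 0.121 before regression exceeds the width of the shuffled range, as regional differences between the lines, such as copy number, would give. Such differences are therefore a candidate explanation for part of the genes that differ between the lines, as a hypothesis, and no DNA was measured.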

How the results depend on the processing

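The scaling alternatives, TPM without mitochondrial genes and protein-coding genes alone were chosen only after the data were examined. The planned count-model alternatives (edgeR with other factors, DESeq2, voom) were not run, as the files hold TPM. Leaving out 1 library leaves its group with 1, assumed to vary like the others. Tested against a fold of 1.5, fewer genes passed, as that test asks for more: 346 (299 higher, 47 lower) for parental MAL3-101 against DMSO, 1604 (435, 1169) for resistant against parental MAL3-101, and 1244 (492, 752) for resistant MAL3-101 against DMSO. With 1 library left out, the first comparison gave 3169 to 7684 genes (1801 to 4513 higher, 1368 to 3458 lower), the second 2124 to 3963 higher genes, and the third 5001 to 8640 genes (1917 to 3931 higher, 2981 to 5069 lower). Camera with an estimated correlation called 0, 0 and 0 lists (3, 3 and 3 at an unadjusted p under 0.05), and fry 17, 22 and 15, against 15, 17 and 9. A larger correlation is argued against as the cause for called lists whose estimate lay below the preset 0.01. These were the tRNA synthetases (-0.016), interferon-stimulated genes (-0.030) and BCL2 family genes (-0.032). Estimates for the other called lists lay above the preset. The largest were 0.836 for mitochondrial mRNAs, 0.619 for replication and G1/S genes and 0.606 for ribosome biogenesis genes. For such lists camera's adjusted p at the preset can be too small. For the other lists the cause was not tested, nor was the part that the 3 residual degrees of freedom of the fit play in that setting. A call lost there therefore does not show that a list did not move. Of the called lists, 10, 13 and 8 kept their call in the settings run for lists other than the estimated correlation (not run for lists were the fold threshold and only the libraries compared), where mitochondrial mRNAs count as not kept because they cannot be tested once mitochondrial genes are removed. The correlation of the fold changes of parental and resistant MAL3-101 libraries against DMSO, 0.293, ranged from 0.282 to 0.385 without 1 library and was 0.179 and 0.228 with a different DMSO library for each. With the replicate letter as a block, 5782, 8204 and 7303 of the genes called without it were called. The main fit pools the spread of the DMSO pair, the widest, with that of the other groups. Fitted to only the 4 libraries compared, 4792, 10116 and 6770 genes were called, against 6181, 8495 and 7662. Of the named genes, DNAJB1, not called in resistant MAL3-101 against DMSO, changed sign, to 0.0443 after median-ratio and 0.00977 after upper-quartile scaling. Median-ratio and upper-quartile scaling moved the median of all genes by less than 0.1 in each comparison. Read depth is unknown, so what it limits cannot be given.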

Other observations

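The tests on runs of genes and on the share of the rise were chosen after the results were seen. Members and targets of the Wnt, Notch and Hedgehog pathways gave 11 higher and 8 lower of 21 tested genes in resistant MAL3-101 against parental DMSO, without a call (adjusted p = 0.183 by camera). WNT5B rose from 21.5 ± 6.75 TPM to 120.3 ± 3.66 TPM and AXIN2, a feedback target of Wnt signalling, from 8.77 ± 3.61 TPM to 31.9 ± 0.170 TPM, while the Wnt inhibitor DKK1 went from 2.41 ± 0.396 TPM to 0.135 ± 0.00707 TPM. FGF7, a growth factor, fell from 57.9 ± 8.22 TPM to 2.92 ± 0.106 TPM, and IGFBP2, which binds insulin-like growth factors, from 77.3 ± 9.52 TPM to 2.42 ± 0.389 TPM. COL3A1, a fibrillar collagen, rose from 30.4 ± 2.70 TPM to 134 ± 0.884 TPM while COL1A1 went from 9.62 ± 2.06 TPM to 2.19 ± 0.417 TPM.

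Several other lists were not called in any of the 3 comparisons by camera, or held fewer than 5 tested members. Oxidative stress targets of NRF2 gave 4 rises, 8 falls and 11 not past the test among 23 genes (4 rises and 10 falls adjusted over the list alone) in parental MAL3-101 against DMSO, with a median of -0.13 and a downward test but a mean of 0.06. In the same comparison autophagy and lysosome genes gave 11 rises, 6 falls and 18 not past the test among 35 genes (12 rises and 6 falls adjusted over the list alone), and fatty acid enzymes 6 rises, 2 falls and 6 not past the test among 14 genes (the same adjusted over the list alone). Glycolysis and hypoxia genes gave 7 higher, 15 lower and 7 not past the test among 29 genes (the same adjusted over the list alone) in resistant MAL3-101 against DMSO, and extracellular matrix and TGF-beta genes 10 higher, 16 lower and 4 not past the test among 30 genes (10 higher and 17 lower adjusted over the list alone). Histone transcripts gave 1 higher, 6 lower and 7 not past the test among 14 genes (1 higher and 7 lower adjusted over the list alone) between resistant and parental MAL3-101 libraries, and fibroblast markers 3 higher, 4 lower and 1 not past the test among 8 genes (3 higher and 5 lower adjusted over the list alone). In the comparisons given here, fry called autophagy genes (adjusted p = 0.043) and fatty acid enzymes (adjusted p = 0.005) upward. It called glycolysis genes (adjusted p = 0.008) and histone transcripts (adjusted p = 0.034) downward. Fibroblast markers were called upward by fry (adjusted p = 0.011), against a median of -0.57. Fry also called some of these lists in other comparisons, among them histone transcripts upward in parental MAL3-101 against DMSO (adjusted p = 0.029). Metallothioneins held 3 tested members, endothelial markers 3, neural markers 2 and blood markers 1.

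Runs of neighbouring genes stood out when the log2 fold change of resistant MAL3-101 against DMSO libraries was averaged as a median over windows of 41 genes. The longest lay between GTDC2 and SMIM4: of 130 genes, 111 were lower in resistant cells and 1 was higher, with a median of -0.82. The same genes had a median of -0.10 in parental MAL3-101 against DMSO. Between SLC12A2 and HARS 65 of 82 genes were lower and 2 higher, and between AK4 and PKN2 47 of 56 were lower and 0 higher by limma's test. Between RPL13AP20 and TMTC1, 38 of 56 genes were higher and 5 lower, with a median of 0.60. That run was also higher in parental MAL3-101 against DMSO, with a median of 0.22, 24 genes higher and 3 lower, and its median between resistant and parental MAL3-101 was 0.35. Windows beyond 200 shuffled orders made up 6.62% of windows in this comparison and 0.428% in parental MAL3-101 against DMSO.

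Different shares of the parental rise of the gene lists were present in resistant cells. Among genes that rose at least 2-fold in parental MAL3-101 libraries, the median share of the log2 rise present in resistant libraries was 0.365 over 32 ATF4 and CHOP targets and -0.0936 over 25 heat shock and immediate-early genes. The difference was 0.458, with a permutation p of 1e-05, the smallest that 100000 resamples can give (two-sided), and genes are not independent replicates. It was 0.358 against the 9 heat shock genes alone (permutation p = 9.7e-04), 0.179 against 14 endoplasmic reticulum genes (permutation p = 0.017) and 0.451, with heat shock and immediate-early genes pooled, after median-ratio scaling. Resistant cells with drug may therefore hold more of the ATF4 branch than of the HSF1 branch of the parental response, as a hypothesis: the tests rest on the same libraries that showed the pattern, and resistant cells without drug would be needed to tell a response from a raised baseline.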
